A study of Mus musculus with 6 samples.

How the data were processed

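The data are 6 RNA sequencing libraries of sorted splenic GC B cells, 3 WT and 3 cKO, grouped by the titles in the labels. Total RNA was harvested with a column kit and libraries followed Illumina's usual protocol, per the labels' protocols, which name no poly(A) selection or rRNA removal. The submitters' processing notes name TopHat2, HISAT2, HISAT, SAMtools, HTSeq and DESeq2, without versions, roles or order, and the mm10 genome. The annotation release, the strand setting and any treatment of reads that match several places are not given in the sources used here. Both TopHat2 and HISAT2 are aligners, and whether all libraries went through the same aligner is not given.

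The authors deposited 1 table of 19680 genes. Its 6 library columns hold a signal per gene that is never negative, deposited as counts divided by a size factor per library, and its mean column equals the mean of the 6 columns. The authors' log2 fold change and its standard error, their test score (a Wald statistic) and their p-value and adjusted p-value stand beside these, per the file headers, and are quoted only as the authors' deposited table. An adjusted p is empty for 8022 genes and stays so here. Gene positions were read from GENCODE M21 (GRCm38, the assembly that mm10 names), in which 19563 of the gene identifiers were found. Whether the authors counted on that release is not given in the sources used here.

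Every value in a column was a whole multiple of the column's smallest value (100% of values in each library, within a tolerance of 0.01 read), so read counts could be recovered: 10339054, 5160902 and 6528052 reads in WT replicates 1 to 3 and 9657005, 3019152 and 3082897 in cKO replicates 1 to 3. A single read is worth 0.506 to 1.06 normalized counts in WT and 0.542 to 2.04 in cKO, so genes of low count are measured least precisely in cKO replicates 2 and 3. Floors for genes with 0 reads use 3 counts over the group and cover counting error only, since the reads carry no molecular identifiers.

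The planned test for deposited counts was edgeR's quasi-likelihood test. Because the table holds normalized values, the test planned for that case was used: limma 3.58.1 in R 4.3.3 with a mean-variance trend on log2(value + 1), over the 14678 genes with a mean of at least 1, all 6 libraries, genotype alone in the model, and Benjamini-Hochberg adjusted p under 0.05. Fold changes on this scale understate the change of genes with low values. Fold differences are 2 to the power of the fitted log2 difference, so they can differ from the ratio of the group means. Only the bound for Efcab3 is a ratio of a group mean to a floor. Count tests on the recovered reads (edgeR 4.0.16, DESeq2 1.42.0 and limma-voom) were added after the data were seen. Both tests were tried on simulated libraries with the spread estimated from these 6 and 200 changed protein-coding genes, none of low count. There limma recovered 42% of genes changed 2-fold and 96% of those changed 4-fold and called 10 unchanged genes among 14632 tested. In the same simulation edgeR recovered 41% and 97% with 8 unchanged genes called among 10846. The simulation drew each gene independently and held no difference between replicate 1 and the other libraries. These shares therefore do not give the power of the test in the real libraries.

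Gene lists were fixed before the data were examined: SUMO pathway, antibody diversification, PAX5-activated and PAX5-repressed genes, GC B cell identity, dark zone, light zone and CD40 NF-kB, plasma cell and secretory, naive or memory B, G2/M, S phase and replication, p53 targets, BCL2 family, interferon response, hypoxia and glycolysis, oxidative phosphorylation, MYC targets and nucleolus, immediate early and stress, 8 lists of other cell types, immunoglobulin heavy constant genes and sex genes. The 26 lists with at least 3 tested genes, the last pair left out, were tested with limma's camera at a preset correlation of 0.01, with an estimated correlation and with fry beside it. The lists share members, such as the mitotic genes of the dark zone list. Of these lists 1, and a few single genes, are not reported here. Per library, a list's level is the median of its members' log2 deviations from their mean over the 6 libraries, compared with an exact two-sided permutation test, which cannot go below 0.1 for 3 against 3.

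Genes named in the text follow a rule fixed before the data were examined. It takes Senp1, Pax5 and the sort genes Ptprc, Cd38 and Fas. It adds up to 12 called genes per direction or, since none were called, the 10 with the smallest unadjusted p. Predicted genes with Gm or Rik names, antibody and T cell receptor segments and pseudogenes were left out of these. From each list the 4 members with the smallest p could be named. Genes named otherwise are said to be chosen after their values were seen.

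The replicate numbers are shared by the groups, and whether they pair the libraries was checked from the correlation of deviations from the group means before the fits were compared. Replicate 1 of both groups differed from the other 4 libraries in depth, in the mitochondrial share and in reads on pseudogenes, so values are also given within replicate 1 and within replicates 2 and 3, and fits with a term for replicate 1 were added. The 17 settings chosen before the data were examined were the replicate block, quantile normalization, library totals alone, no filter and a stricter filter (mean of at least 5), a pseudocount of 0.1, each library left out, immunoglobulin genes left out, stricter thresholds, an estimated correlation and fry. The 10 settings added afterwards were the count tests, the term for replicate 1, that term with cKO replicate 2 left out, removal of each library's trend with GC content (a loess curve over genes with a mean of at least 20) and replicates 2 and 3 alone. Genes that share reads with near-identical copies, such as mitochondrial genes and their nuclear copies or the antibody constant genes, and genes that overlap others, such as Efcab3 with Gm11639 on the same strand, are uncertain because the counting rule is not given.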

Results

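Gene expression was measured by RNA sequencing in germinal center (GC) B cells, the dividing B cells that mutate and switch their antibody genes during an immune response. The cells were sorted from mouse spleen as B220-positive, CD38-negative and FAS-positive cells. Sorting took place on day 14 after 100 µg of NP-CGG, a protein antigen carrying a small hapten, had been injected into the abdominal cavity of C57BL/6 mice aged 6 to 8 weeks. The 3 WT libraries came from mice whose Senp1 gene is flanked by loxP sites, and the 3 cKO libraries from such mice that also carry Cγ1-Cre, a Cre recombinase active in B cells that respond to antigen. Senp1 encodes a protease that removes the small modifier protein SUMO from its targets. The comparison of cKO with WT asks which transcripts change in these cells when Senp1 is deleted, and the series title names the transcription factor PAX5. The WT libraries held 10339054, 5160902 and 6528052 gene-assigned reads and the cKO libraries 9657005, 3019152 and 3082897, in order of replicate number. Values below are normalized counts as mean ± SD with n = 3 libraries per group, and the labels do not say whether each library came from its own mouse, so p-values measure the spread between these libraries. The first principal component (47.6% of the variance) set replicate 1 of both groups, at -40.2 and -35.2, apart from the other libraries, at 1.07 to 30.9.

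Senp1 was lower in every cKO library than in every WT library. It measured 891 ± 23.7 normalized counts in WT (915, 868 and 891) and 399 ± 26.3 in cKO (373, 425 and 398), a 2.24-fold difference. Senp1 (ENSMUSG00000033075) lies on chromosome 15 at 98038744 to 98093744 of GRCm38, and its reads were not split by exon, so the remaining signal includes any transcript that lacks the deleted part. Its log2 fold change was -1.16 (95% confidence interval -1.44 to -0.88), with a limma adjusted p of 0.111 over 14678 genes, which does not pass 0.05. Adjusted over the SUMO list alone it was 0.000197. Within replicate 1 the log2 difference was -1.29, and within replicates 2 and 3 it was -1.09. A term for replicate 1 against the others, added after the data were seen, brought the limma adjusted p to 0.016, and over 23 alternatives it ranged from 3.30e-14 to 0.661.

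No gene passed the test at this spread: limma called 0 genes higher and 0 lower in cKO. At an unadjusted p under 0.05 there were 438 genes higher and 318 lower, and which direction held more depended on the setting: library totals alone gave 275 and 403, and leaving out cKO replicate 2 gave 323 and 386. The counts were 726 and 637 without cKO replicate 1, 192 and 153 without WT replicate 2, and 681 and 664 with the term for replicate 1. The groups did not overlap for 11.6% of the genes, where chance gives 10%. With reads recovered from the normalized counts, edgeR called 0 genes (611 at an unadjusted p under 0.05), limma-voom 0 (558) and DESeq2 15 higher and 5 lower (559). The authors' deposited table lists 16 genes as higher and 7 as lower at an adjusted p under 0.05, among them Senp1. With the term for replicate 1, limma called 3 genes (Senp1, Cacna1h and Cfap74), edgeR 4 and DESeq2 79, while replicates 2 and 3 alone gave 0 by limma. With that term and cKO replicate 2 left out, also chosen after the data were seen, limma called 6 genes higher and 10 lower (738 and 848 at an unadjusted p under 0.05).

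The 10 genes picked for the smallest unadjusted p had no overlap between the groups. Besides Senp1, the lower gene was Lhfpl4, a tetraspan protein of inhibitory synapses, at 104.6 ± 11.6 in WT and 15.7 ± 7.86 in cKO. Higher in cKO were the glutathione transferases Gstt1 (72.9 ± 39.7 and 299 ± 39.7) and Gstt2 (267 ± 52.4 and 726 ± 156), which conjugate glutathione to reactive compounds. Cfap74, a gene of cilia and flagella, measured 73.3 ± 19.1 in WT and 279.9 ± 66.4 in cKO, and the atypical protein kinase C gene Prkcz 17.1 ± 4.92 and 85.7 ± 27.7. The calcium channel gene Cacna1h was 2.99-fold higher (281 ± 79.9 and 841 ± 253), the chromatin remodeler Chd3 1.77-fold (523 ± 42.5 and 926 ± 79.1) and Shisa8 2.66-fold (46.8 ± 0.893 and 128 ± 30.4). Efcab3 had 0 reads in all 3 WT libraries and 49 reads over the cKO libraries (19.8 ± 4.92 normalized counts). Against a floor of 3 reads over the WT group, Efcab3 was at least 27.0-fold higher. None of the 10 passed the limma adjustment over all genes (adjusted p of 0.111 to 0.513). All 10 passed by DESeq2 on the recovered reads (adjusted p of 2.78e-09 to 0.00201), and all 10 are called in the authors' deposited table (adjusted p of 2.38e-09 to 0.00173). The log2 fold changes of these genes are the same in both (-1.17 for Senp1), so these are not separate support. The 10 were also picked by p in the same libraries.

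**Figure D1:**
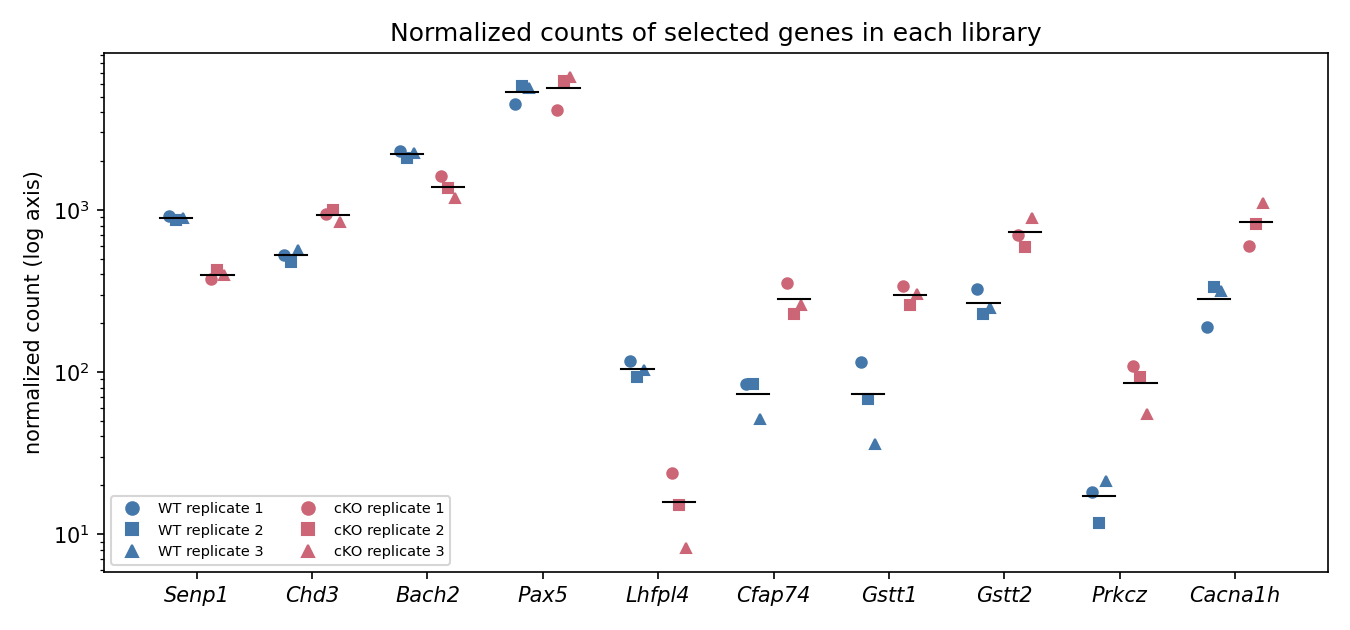
Normalized counts per library (log axis) of 10 genes in WT (blue) and cKO (red), with marker shape for the replicate number and a black line at the group mean (n = 3). Senp1 and Lhfpl4 sit lower in all cKO libraries, Chd3, Cfap74, Gstt1, Gstt2, Prkcz and Cacna1h sit higher, and Pax5 overlaps between the groups.

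Pax5, the transcription factor that keeps B cell identity, measured 5321 ± 735 in WT and 5670 ± 1341 in cKO, a difference within the spread of the libraries. Bach2, a repressor of plasma cell differentiation, measured 2220 ± 119 and 1387 ± 218, lower in every cKO library. The log2 fold change was -0.69 ± 0.15 (SE) for Bach2 and 0.07 ± 0.21 for Pax5. Their limma adjusted p-values over all genes were 0.813 and 0.981, so limma called neither. Bach2 passed by DESeq2 with the term for replicate 1 (adjusted p = 2.40e-05). It missed the threshold by DESeq2 without the term (0.0520) and by limma with it (0.129), and its adjusted p ranged up to 0.999 over 23 alternatives. In the authors' deposited table Bach2 is called lower (adjusted p = 0.0447). Within replicate 1 and within replicates 2 and 3, respectively, the log2 difference was -0.52 and -0.77 for Bach2 and -0.11 and 0.16 for Pax5. Pax5 (ENSMUSG00000014030) changed sign with the scaling: its log2 fold change was -0.020 after quantile normalization and -0.0083 with library totals alone, and it also turned without WT replicate 1 (-0.048), cKO replicate 2 (-0.012) or cKO replicate 3 (-0.057).

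Over the 26 lists, 6 members passed by limma when adjusted over the list alone, a gene in several lists counted in each. Over all fits that count ranged from 1, without WT replicate 2, cKO replicate 2 or cKO replicate 3, to 35, by DESeq2 with the term for replicate 1. It was 17 without cKO replicate 1 and 21 by limma with the term. Of 28 PAX5-activated genes 0 passed over all genes and 2, both lower and among them Bach2, when adjusted over the list alone, while Siglecg (1215 ± 198 and 1715 ± 353) had a higher cKO mean. The 15 PAX5-repressed genes had 0 calls on either scale, with Ccr2 at 3.97 ± 2.77 and 16.8 ± 4.96 and the plasma cell regulator Prdm1 at 89.2 ± 26.6 and 58.6 ± 14.8. In the antibody diversification list of 37 genes 0 passed on either scale, and Polq (308 ± 26.4 and 215 ± 39.4), Atm (783 ± 13.4 and 615 ± 68.5) and Rif1 (768 ± 81.7 and 616 ± 28.5) had lower cKO means. In the SUMO pathway list of 26 genes, Senp1 alone passed when adjusted over the list alone, while Senp5 (186 ± 26.3 and 140 ± 19.9), Rnf4 (806 ± 54.4 and 690 ± 107) and Uspl1 (335 ± 34.7 and 406 ± 64.3) did not. None of these 4 lists was called by limma's camera (adjusted p of 0.656, 0.483, 0.0511 and 0.0982 in that order). At the preset correlation, the antibody diversification list (median -0.097) was called lower without WT replicate 3 (-0.13, adjusted p = 0.000915) or cKO replicate 1 (-0.18, 0.000538). It was also called lower with library totals (-0.18, 0.0170), without immunoglobulin genes (0.0429), with the replicate block (0.0149) and with the term for replicate 1 (0.0136). The same held in replicates 2 and 3 alone (-0.14, 0.00543), while without cKO replicate 2 the median of this list was -0.014 (0.733). The SUMO list (median -0.071) was called lower without WT replicate 1 (-0.11, 0.0478), with library totals (-0.15, 0.0213) and in replicates 2 and 3 alone (-0.068, 0.0467). With an estimated correlation over all 6 libraries the adjusted p was 0.747 for antibody diversification and 0.720 for the SUMO list. The SUMO list passed fry's test for change in either direction with Senp1 in it (adjusted p = 1.49e-07) and not with its other 25 genes alone (0.786), a test added after the data were seen. Fry called 0 lists for change in a single direction (smallest adjusted p = 0.792). Neither test compares a list with other genes.

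As groups, genes of the dark zone, the GC compartment where B cells divide and mutate, and of the cell cycle had lower cKO values, and light zone genes had higher ones. Camera called 8 pathway lists at a preset correlation between genes of 0.01, and with an estimated correlation each of the 8 had an adjusted p of 0.720. cKO replicate 2, with the lowest dark zone, S phase and G2/M medians, also held the most transcripts of T cells (median 2.26 log2 units above the mean of the libraries) and macrophages (1.74). The dark zone median per library was 0.64, 0.31 and -0.23 in WT and 0.38, -0.77 and -0.24 in cKO, in order of replicate number, and the mitochondrial share of reads 2.71%, 7.92% and 9.83% and 3.66%, 12.3% and 19.1%. So the 3 libraries with the highest medians had the lowest mitochondrial shares. Replicate 1 of both groups was among these. Its low shares may come from how reads on mitochondrial genes and their nuclear copies were counted, which was not tested. The share of 5 rRNA-like transcripts, chosen after their values were seen, was higher in all 3 cKO libraries than in WT. All 21 dark zone genes had negative log2 fold changes (median -0.44, camera adjusted p = 2.86e-06), among them Hmmr (562 ± 156 and 344 ± 159) and Foxo1 (1350 ± 165 and 1086 ± 60.9). The same held for all 28 G2/M genes (median -0.42, adjusted p = 9.96e-06), such as Top2a (5199 ± 1706 and 3609 ± 1442), and for 30 of 33 S phase genes (median -0.27, adjusted p = 5.01e-06), such as Mcm4 (2451 ± 331 and 1914 ± 333) and Pola1 (893 ± 154 and 649 ± 170). Many dark zone genes, Hmmr and Top2a among them, are also in the G2/M list, so the dark zone and G2/M results are not separate. GC B cell identity genes were lower in 20 of 26 (median -0.18, adjusted p = 0.000467), with Mybl1 at 1729 ± 318 and 1245 ± 176 and Gna13 at 2202 ± 127 and 1777 ± 182. Light zone and CD40 NF-kB genes were higher in 28 of 32 (median 0.25, adjusted p = 0.000316), with Nfkb2 at 897 ± 94.7 and 1141 ± 151 and Relb at 249 ± 34.5 and 316 ± 11.4. Naive or memory B genes were higher in 23 of 24 (median 0.57, adjusted p = 0.00057), with Klf2 at 162 ± 99.7 and 381 ± 233 and Cr2 at 1565 ± 529 and 2222 ± 355. The groups overlapped for Klf2 and Cr2, but not for Nt5e, the 1 lower gene of this list (log2 fold change -0.61). MYC targets and nucleolar genes were higher in 27 of 28 (median 0.14, adjusted p = 5.21e-05), with Rrp12 at 264 ± 25.5 and 376 ± 60.2 and Srm at 288 ± 19.2 and 400.4 ± 71.9. Immediate early and stress genes were higher in 20 of 20 (median 0.38, adjusted p = 0.000699), with Atf3 at 30.6 ± 18.3 and 65.0 ± 24.4 and Ier5 at 427 ± 247 and 643 ± 227.

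With an estimated correlation the smallest adjusted p over the 26 lists was 0.720, so no call held. No member passed over all genes by limma, and over the list alone 1 did in the dark zone list and 2 in GC identity, among them Bach2. The list medians per library overlapped between the groups, with an exact two-sided permutation p of 0.4 for the dark zone list, where 0.1 is the smallest possible. Without cKO replicate 2, camera called 1 list in place of 10: the MYC list (adjusted p = 1.45e-05), while the dark zone (median -0.14, adjusted p = 0.1003), S phase (0.280), G2/M (0.664), GC identity (0.1296), light zone (0.109), naive or memory B (0.664) and immediate early lists (0.0980) lost theirs. The MYC call was lost without cKO replicate 3 (adjusted p = 0.131), immediate early also there (0.239), and G2/M (0.150), light zone (0.212), naive or memory B (0.172) and immediate early (0.332) without WT replicate 1. Leaving out cKO replicate 2 also makes replicate 1, which stood apart, 1 of 2 cKO libraries. With a term for replicate 1 beside it, all 8 lists were called at the preset correlation, among them the dark zone (median -0.22, adjusted p = 7.95e-06), G2/M (-0.19, 0.00194), S phase (-0.17, 0.00904) and naive or memory B lists (0.21, 0.0369). Each of the 10 called lists lost its call without at least 1 library. With single libraries left out, the medians ranged from -0.84 to -0.14 for the dark zone, -0.74 to -0.070 for G2/M, -0.45 to -0.12 for S phase, -0.34 to -0.067 for GC identity, 0.079 to 0.53 for the light zone, 0.072 to 0.95 for naive or memory B, 0.035 to 0.22 for MYC and 0.082 to 0.97 for immediate early genes. The values nearest to 0 came without cKO replicate 2 for the dark zone, G2/M, S phase, GC identity and naive or memory B lists, without WT replicate 1 for the light zone and immediate early lists, and without cKO replicate 3 for the MYC list. The values farthest from 0 came without cKO replicate 1, except in the light zone list, where they came without WT replicate 3. Within replicate 1 and within replicates 2 and 3, respectively, the median differed by -0.26 and -0.55 for the dark zone, -0.22 and -0.52 for G2/M, and 0.43 and 0.58 for naive or memory B genes.

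**Figure D2:**
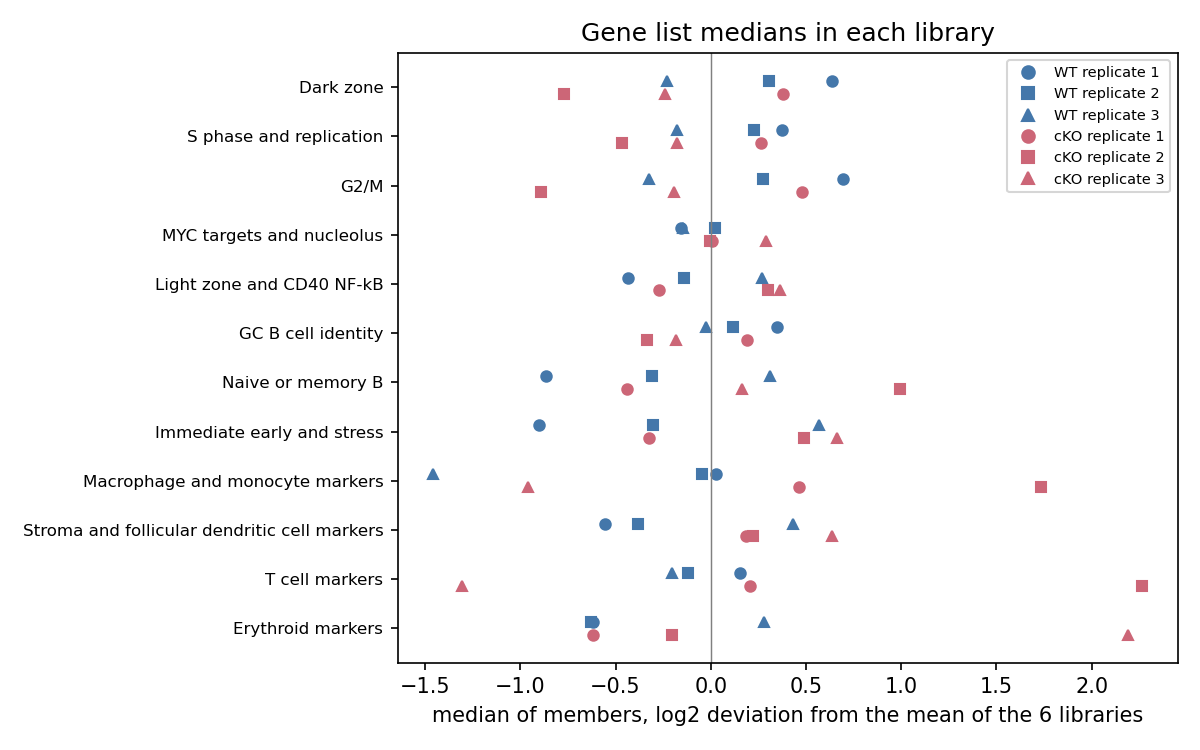
Median log2 deviation of each list's members from the mean of the 6 libraries, per library, for the 10 lists called by camera and for T cell and erythroid markers (blue WT, red cKO, marker shape for the replicate number). cKO replicate 2 has the lowest dark zone, S phase and G2/M medians and a T cell median of 2.26, and the groups overlap in every list shown.

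The remaining pathway lists gave no call over all 6 libraries, and 4 gained a call at the preset correlation in other fits. p53 targets had a median log2 fold change of 0.15 (camera adjusted p = 0.0942), with the repair nuclease Ercc5 at 62.9 ± 11.2 in WT and 115 ± 34.4 in cKO, and were called higher without WT replicate 3 (median 0.37, adjusted p = 0.00176). Interferon response genes (median 0.02, adjusted p = 0.236) included Ifit3 at 3.36 ± 2.47 and 11.9 ± 5.29 and Isg15 at 14.3 ± 7.76 and 52.5 ± 36.6, and their median differed by -0.54 within replicate 1 and 0.55 within replicates 2 and 3. They were called higher without WT replicate 1 (median 0.20, adjusted p = 0.0478) or cKO replicate 1 (0.28, 0.0167) and in replicates 2 and 3 alone (0.49, 0.000691). Hypoxia and glycolysis genes (adjusted p = 0.567) had a median of 0.03 but a mean of -0.08, the sign of the test, with Hif1a at 952 ± 109 and 752 ± 83.7. Oxidative phosphorylation genes (median -0.06, adjusted p = 0.192), plasma cell and secretory genes (0.05, 0.567) and the BCL2 family (0.06, 0.746) had no member past the test on either scale, with Sdha at 1631 ± 142 and 1404 ± 148, Ell2 at 583 ± 106 and 451 ± 51.7, and Bcl2l1 at 144 ± 16.1 and 169 ± 20.3. Oxidative phosphorylation genes were called lower without WT replicate 3 (median -0.17, adjusted p = 0.000275) or cKO replicate 1 (-0.18, 0.000205), and plasma cell and secretory genes higher in replicates 2 and 3 alone (0.17, 0.0467). With an estimated correlation over all 6 libraries the adjusted p was 0.720 for p53 targets and 0.840 for the interferon, oxidative phosphorylation and plasma cell lists.

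Markers of other cell types varied between single libraries of a group. T cell markers (camera adjusted p = 0.173, or 0.840 with an estimated correlation) stood at 2.26 log2 units from the mean of the libraries in cKO replicate 2 and at -1.31 in cKO replicate 3, with Cd3e at 140 and 6.13 normalized counts there and 5.98 to 20.7 in WT. Their median was 0.57, and without cKO replicate 3 it was 1.40 and called higher at the preset correlation (adjusted p = 4.93e-08). With cKO replicate 2 left out and a term for replicate 1 it was -0.26 and called lower at that correlation (0.00846). Macrophage and monocyte markers were called higher (15 of 18 positive, median 0.53, adjusted p = 0.00752, or 0.720 with an estimated correlation), but without cKO replicate 2 their median was -0.08 (adjusted p = 0.733), and the call was also lost without WT replicate 3 (0.276) or cKO replicate 1 (0.0615), or without cKO replicate 2 in the fit with the term (0.903). Their median was 0.95 without WT replicate 2 and 1.15 without cKO replicate 3. The 5 tested stroma and follicular dendritic cell markers were called higher (median 0.78, adjusted p = 0.0396, or 0.720 with an estimated correlation), with Pecam1 at 354 ± 127 and 440 ± 174. They lost the call without WT replicate 1 (median 0.62, adjusted p = 0.231), WT replicate 2 (0.23, 0.146), cKO replicate 1 (0.62, 0.0615), cKO replicate 2 (1.06, 0.173) or cKO replicate 3 (0.65, 0.0924). The call was also lost after quantile normalization (0.64, 0.0622), with no filter (0.28, 0.413), with a stricter filter (0.30, 0.153), with the GC trend removed (0.62, 0.0785), in replicates 2 and 3 alone (0.81, 0.148) and with the term and cKO replicate 2 left out (0.98, 0.0876). Erythroid markers (adjusted p = 0.234) were 2.19 above the mean in cKO replicate 3. Neutrophil (0.746), dendritic cell (0.216) and NK markers (0.567) were not called over all 6 libraries, where an estimated correlation gave 0.883, 0.720 and 0.843. At the preset correlation, neutrophil markers (median 0.11) were called lower without WT replicate 3 (-0.94, adjusted p = 0.0257), NK markers (0.16) higher without WT replicate 2 (0.55, 0.0170) or cKO replicate 3 (0.90, 0.0397), and dendritic cell markers (0.55) higher without cKO replicate 3 (0.65, 0.0397). Of the platelet list 1 gene was measured (Itga2b, 2.02 ± 1.17 and 2.90 ± 1.11). The sort genes did not separate the groups: Ptprc, which encodes B220, measured 7584 ± 994 and 6831 ± 1243, Cd38 71.0 ± 34.5 and 94.1 ± 67.7, and Fas 556 ± 41.5 and 537 ± 75.3. The sign for Cd38 and Fas turned when single libraries were left out.

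Immunoglobulin heavy chain constant genes were taken as levels. Ighg1 was the most abundant at 36286 ± 4046 normalized counts in WT and 36174 ± 2829.9 in cKO, 64.1% and 61.3% of heavy constant reads. Ighe had 0.142% ± 0.0305 of these reads in WT and 0.0472% ± 0.0153 in cKO, without overlap (exact two-sided permutation p of 0.1, the smallest that 3 against 3 allows), and 83.9 ± 31.3 and 27.9 ± 2.35 normalized counts. Of all genes tested, 11.6% had no overlap in normalized counts, where chance gives 10%. A read was worth 1.90 and 2.04 normalized counts in cKO replicates 2 and 3, so Ighe rests on few reads there. Of the 8 constant genes 0 passed the limma test over all genes and 1 (Ighe, lower) adjusted over the list alone. Ighe passed over all genes by DESeq2 with the term for replicate 1 (adjusted p = 0.0284), and Ighg2b by limma with that term and cKO replicate 2 left out (log2 fold change -1.12, adjusted p = 0.0260). The share of Ighe differed by -0.103 percentage points within replicate 1 and -0.0908 within replicates 2 and 3. The shares of Ighm (10.6% ± 5.84 and 14.6% ± 3.38), Igha (16.7% ± 8.06 and 18.2% ± 15.9), Ighg2b (4.35% and 3.995%), Ighg2c (3.12% and 0.710%), Ighg3 (0.677% and 0.438%) and Ighd (0.362% and 0.730%) overlapped between the groups. The Y-linked genes Ddx3y (612 ± 179 and 601 ± 178), Kdm5d (216 ± 9.64 and 194 ± 30.7), Eif2s3y (447 ± 165 and 376 ± 80.5) and Uty (117 ± 36.6 and 90.1 ± 25.6) were read in both groups.

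RNA composition differed between libraries too. The 5 rRNA-like transcripts in the plot of shares per library, chosen after their values were seen and with the protein-coding gene Lars2 among them, took 0.129% ± 0.0605 of reads in WT and 0.566% ± 0.197 in cKO (exact two-sided permutation p of 0.1), a difference of 0.195 percentage points within replicate 1 and 0.558 within replicates 2 and 3. Because of that choice, the p for their share does not test a difference between the groups. Mitochondrially encoded genes took 6.82% ± 3.69 and 11.7% ± 7.73 (exact p of 0.4), with 2.71% and 3.66% in replicate 1 of WT and cKO. Their share was higher in cKO by 0.953 percentage points within replicate 1 and by 6.83 within replicates 2 and 3. The exact test does not allow for the difference between replicate 1 and the others.

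**Figure D3:**
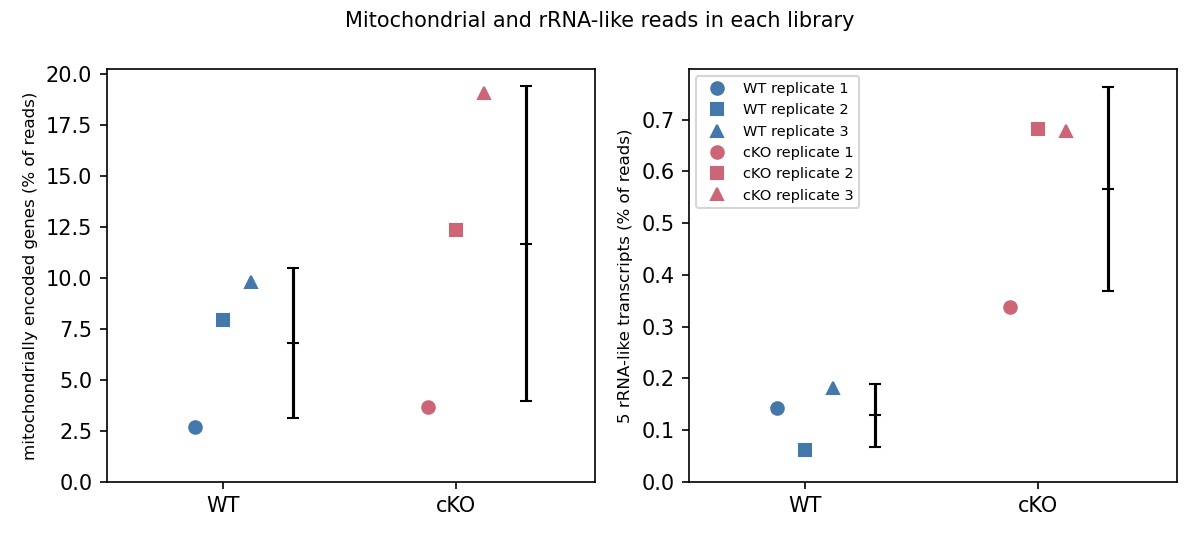
Percent of gene-assigned reads in mitochondrially encoded genes (left) and in 5 rRNA-like transcripts, Gm42418, Gm26917, Gm15564, Gm23935 and Lars2 (right), per library (blue WT, red cKO, marker shape for the replicate number), with the group mean ± SD in black (n = 3). The 3 cKO libraries lie above the 3 WT libraries for the rRNA-like share, and the mitochondrial shares overlap.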

Additional observations from a re-analysis of the deposited data

How the results depend on the processing

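The fits with a term for replicate 1, the GC trend, the count tests and replicates 2 and 3 alone were chosen after the data were seen. The other settings were planned. Of the count tests, edgeR alone had been planned, for deposited counts, and all of them were run on recovered reads. Senp1 (log2 fold change -1.24 to -1.08) was lower in cKO under all 23 alternatives fitted per gene. Counts of 0 genes higher and 0 lower held in every setting except these: DESeq2 (15 and 5), DESeq2 with a term for replicate 1 (53 and 26), edgeR with that term (2 and 2), limma with that term (2 and 1), the same with the GC trend removed (2 and 1), limma with that term and cKO replicate 2 left out (6 and 10), and the replicate block (1 higher, Cacna1h). List members past the test over all genes went from 0 to 5 with DESeq2 or with limma, the term and cKO replicate 2 left out, 11 with DESeq2 and the term, and 1 with edgeR and the term, limma and the term, or the GC trend removed and the term. Senp1 passed in edgeR with the term (-1.16), DESeq2 (-1.17), DESeq2 with the term (-1.17), limma with the term (-1.16), the same without cKO replicate 2 (-1.21) and the GC trend removed with the term (-1.08). Residual spread is smaller by construction where a term takes up the replicate 1 difference; otherwise the cause was not tested. The replicate block changed no other count of calls by over 1.5 times except members adjusted over the list alone (6 to 25), and called the antibody diversification list lower (adjusted p = 0.0149). The labels' protocol calls the mice paired without tying replicate numbers to pairs, and same-numbered deviations correlated at 0.49, 0.05 and 0.20 across genes (0.73, 0.062 and 0.32 over genes with a mean of at least 20), so the numbers were not taken as pairs, which leaves pairing open; WT replicate 2 correlated best with cKO replicate 3. Camera's 10 lists became 0 with an estimated correlation and fry called 0, while single libraries left out gave 1 to 13, the lowest without cKO replicate 2. Library totals alone moved the median of all genes to -0.08 and the split at an unadjusted p under 0.05 from 438 higher and 318 lower to 275 and 403. Signs of uncalled genes turned as follows, cause not tested. Pax5 was -0.020 after quantile normalization, -0.0083 with library totals and -0.050 with the GC trend removed, with or without the term, and ranged from -0.057 to 0.28 with a library left out. Ranges with a library left out that crossed 0 were Cd38 -0.42 to 0.95, Fas -0.15 to 0.057, Ighg1 -0.089 to 0.073, Ighg2b -0.87 to 0.57, Ighg2c -3.09 to 0.33, Ighg3 -0.93 to 0.57, Igha -1.07 to 0.85, Ddx3y -0.28 to 0.22, Eif2s3y -0.54 to 0.025, Ngp -0.28 to 2.11, Gzma -0.064 to 1.28, Hba-a1 -0.095 to 1.91, Hbb-bs -0.51 to 1.66, and the neutrophil list median -0.94 to 0.68. With the GC trend removed, with or without the term, Fas was 0.052 and Ddx3y 0.14; Ddx3y was 0.0021 after quantile normalization. By edgeR, edgeR with the term, DESeq2 and DESeq2 with the term, Ighg2b was 0.12, 0.29, 0.10 and 0.29 and Igha 0.52, 0.49, 0.51 and 0.48; Ighg1 was 0.0055, 0.0082 and 0.0063 by edgeR, edgeR with the term and voom, where Cd38 was -0.32. With the term and cKO replicate 2 left out, Cd38 was -0.15, Fas 0.041, Cd3e -0.10, Cd247 -0.11, Thy1 -0.15, Gzma -0.0040, Ighg1 0.042 and the T cell list median -0.26, which camera called. In replicates 2 and 3 alone Ighg1 was 0.034, Ighg2b 0.35, Ighg2c 0.17 and Ighg3 0.85. Of the other values for single genes and lists, 2959 kept their side of the test, 57 gained a call and 29 lost 1. The shallow cKO replicates 2 and 3, where a read is worth 1.90 and 2.04 normalized counts, limit genes of low count.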

Other observations

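The tests of GC content, of histone genes, of pseudogenes and of the dark zone list with a term for replicate 1 were chosen only after the result was seen. RNA classes outside the fixed lists were taken as values, with 0 members past the limma test and no test of a class against the groups. DESeq2 with the term for replicate 1 called 5 mitochondrially encoded genes higher and, of ribosomal protein genes, 2 higher and 1 lower, and limma with that term and cKO replicate 2 left out called 1 mitochondrially encoded gene higher. Replication-dependent histone genes, whose mRNAs end without a poly(A) tail, had a median log2 fold change of 0.73, with 32 of 36 positive and 7 at an unadjusted p under 0.05, while the S phase list had a median of -0.27. Small nuclear RNAs had a median of 0.53 (16 of 23 positive, 1 at that p), small nucleolar RNAs 0.09 (49 of 86, 3), ribosomal protein genes 0.13 (86 of 102, 4) and mitochondrially encoded genes 0.78 (18 of 18, 0). Named after their values were seen, Gm42418 measured 5023 ± 2152 normalized counts in WT and 18277 ± 4527 in cKO, the RNase P RNA Rpph1 16.9 ± 7.16 and 97.4 ± 59.0, and Rn7sk 20.4 ± 18.7 and 185 ± 144 (n = 3). Coro2a, called lower in the authors' deposited table, measured 729 ± 34.3 and 445 ± 54.8, and the protease inhibitor gene Slpi, called higher there, 688 ± 93.9 and 1188 ± 227.

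Some of the genes with the smallest p lie next to each other. Prkcz, Cfap74 and Tmem52 lie within 155260129 to 155470858 on chromosome 4 of GRCm38, and Gstt1, Gstt2, Gstt3 and Ddt within 75771230 to 75837424 on chromosome 10. Of the 100 protein-coding genes with the smallest p, 14 had another of the 100 within 500 kb with the same direction, against a median of 8 in 1000 random lists matched on GC content (permutation p = 0.0799). Across 9799 genes with a mean of at least 20, the log2 fold change was higher at higher GC content (Spearman's rho 0.348 across genes, which are not independent replicates), from a median of -0.11 in the fifth of genes lowest in GC to 0.14 in the highest. Per library, the rho of GC content with the deviation from the mean of the libraries overlapped between the groups (exact two-sided permutation p of 0.3). In order of replicate number it was 0.216, -0.361 and -0.451 in WT and 0.396, -0.0114 and 0.0800 in cKO. So it was higher in cKO within replicate 1 and, without overlap, within replicates 2 and 3, a split that the exact test ignores.

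The dark zone and cell cycle lists had negative medians in cKO that camera called at the preset correlation but not at an estimated one (adjusted p = 0.720 for the dark zone, or 0.655 with the term for replicate 1), and the dark zone medians per library overlapped (exact two-sided permutation p of 0.4). Removing each library's GC trend left the dark zone median at -0.37 against -0.44 (camera adjusted p = 5.11e-06 at the preset correlation), which argues against GC content as the whole cause of the lower median. Without cKO replicate 2, which had Cd3e at 140 normalized counts, the dark zone median was -0.14 (adjusted p = 0.1003), but with a term for replicate 1 as well it was -0.22 and still called (7.95e-06 at the preset correlation). How far other cells in that library account for the difference stays open. Its cells came from the sort for B220-positive, CD38-negative and FAS-positive cells, which did not keep these T cell transcripts out. An effect of Senp1 deletion on these lists remains open as an untested hypothesis, as does a difference between the mice that the labels do not record. The RNA composition of the libraries also remains open and was not tested as a cause. The 3 libraries with the highest dark zone medians had the lowest mitochondrial shares. Replicate 1 of both groups was among these, and its low shares may come from how reads on mitochondrial genes and their nuclear copies were counted. All 3 cKO libraries had higher rRNA-like shares than WT, for transcripts chosen after their values were seen.

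Chosen after their values were seen, 8 transcripts had a median log2 fold change of 2.59: Gm42418, Gm26917, Gm15564, Gm23935 and the protein-coding gene Lars2, taken as rRNA-like, and Rpph1, Rn7sk and Rmrp, which have no poly(A) tail. None passed the limma test (adjusted p of 0.543 to 0.915), while DESeq2 called Gm42418 and Rpph1 higher, and Rn7sk and Gm26917 too with the term for replicate 1, and Gm42418, Gm15564, Lars2 and Rpph1 alone of the 8 had no overlap between the groups. The median was 1.95 with log2 reads as a covariate. With that covariate Gm26917 went from 3.61 to 2.24 and Rmrp from 1.92 to 0.68 ± 0.73 (SE), while Gm15564 went from 2.77 to 2.83. Since the 8 were chosen after their values were seen, this fit cannot decide whether depth was the cause, which stays open. The histone median of 0.73 lay above 99.99% of 10000 random lists matched on expression. Those lists draw genes independently, so the percentile does not measure the spread between libraries or allow for histone genes that vary together. More tailless RNA entering the cKO libraries, from library preparation or from RNA quality, stays possible and was not tested between libraries. Whether Senp1 deletion itself alters these RNAs was not tested, and the small nucleolar RNAs had a median of 0.09.

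Replicate 1 of both groups stood apart: 36.6% of 9819 genes set these 2 libraries apart from the other 4, where chance gives 13.3% and the highest of the 14 other pairs gave 25.03%. The mitochondrial gene mt-Atp8 was at 1.52 and 4.88 normalized counts in replicate 1 and at 1834 to 5055 elsewhere, and Gm28437, a nuclear copy of mitochondrial sequence, at 110 and 150 against 9589 to 32187. The median of 146 processed pseudogenes was -1.31 on the log2 scale in replicate 1 relative to the others, below all of 10000 random lists of protein-coding genes. That is consistent with a different treatment of reads that match several copies. Thinning all libraries to the shallowest gave a pseudogene median of -1.05 against -1.04 (both as log2 CPM). Thinning leaves the expected CPM as it was, so this outcome was set in advance and cannot decide whether depth was the cause of that median. Thinning cannot test other differences between the libraries that go with depth, and no biological explanation was tested.

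With 3 libraries against 3 there are 10 splits, too few for a share under 0.05. The real split called 0 genes by limma, so all 10 splits had to give as many and that count tests nothing. The highest other called 95 (WT replicates 1 and 2 with cKO replicate 1). At an unadjusted p under 0.05 the real split gave 756 genes and the highest other 2563, with 4 of the 10 splits giving as many. Camera called 10 lists in the real split and 15 in the highest other, and 7 splits gave as many. The splits with the most genes keep replicate 1 of both groups together, which points to the structure of these libraries. Within replicates 2 and 3 limma called 0 genes, but that fit has fewer libraries and little power. It gave 1017 genes at an unadjusted p under 0.05, and camera called 13 lists there at the preset correlation. With the term for replicate 1 limma called 3 genes.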
